A study of Zea mays with 4 samples.

How the data were processed

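Total RNA of the maize lines Cm489 and F98908 was hybridised to Affymetrix maize arrays, with 2 arrays per line and 4 in all. Per the labels, the plants were 21 days old and at the 7 leaf stage, grown on potting compost under 16 h of light and 8 h of dark at 50% humidity, and the sampled material is given only as aerial. The labels record amplification, direct biotin labelling and 20 ug of cRNA. The groups and replicate numbers follow the labels. The extract label of F98908 array 2 repeats that of F98908 array 1 (213 ug in both), while the 2 Cm489 arrays have extract labels of their own (177 and 170 ug). Nothing in the labels says that the arrays of a line came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

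The deposited values are on a log2 scale, 1 per probe set and array, and were made with GCRMA per the submitters' processing notes, with a version not given in the sources used here. GCRMA corrects the background from probe sequence, normalises the arrays to a common distribution and summarises the probes of a set. In the deposited log2 values the medians of the 4 arrays lay between 6.65 and 6.67, and the values of each array ran from about 1.0 to between 14.7 and 14.8. Scanner files and detection calls were not used here. Normalising to a common distribution removes any difference in total output between the lines, and values near the lower end have no reliable order. The highest value of 23 control probe sets with no target in the plant was between 2.45 and 2.50 on the 4 arrays. The number of arrays limits the precision.

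The table holds 17734 probe sets, of which 113 are array controls and were left out, leaving 17621. A probe set was tested if its log2 value was over 4 on at least 2 of the 4 arrays, which kept 11263 (63.9%). Gene names came from the platform's annotation, updated through gene numbers to the RefSeq annotation of assembly Zm-B73-REFERENCE-NAM-5.0. Of the maize probe sets, 1452 have 1 gene symbol, 1 has several and was not named, and 16168 are unnamed here. The named probe sets stand for 1108 genes, of which 1060 matched the RefSeq table and 978 have a name other than a locus number. Symbols are those of the tables, whose synonyms differ in age. No genome build is named for the deposited values, so no positions are given.

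The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, F98908 minus Cm489, no replicate block), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The eBayes prior had 1.79 degrees of freedom beside 2 residual ones. Where the mean of the dimmer line lay under log2 4, the fold is given as "at least", computed from the brighter line's mean against log2 4, and the measured means or difference are given beside it.

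Before the data were examined, 31 gene lists were fixed for wall synthesis, leaf cell types, other tissues, stress and metabolism. The available tables hold symbols and synonyms but no gene descriptions, so the patterns meant for descriptions were searched in the symbols too, and 6 lists matched no gene: photosystem, resistance like, ribosomal proteins, circadian, anther and pollen, and transposable elements. Each gene was represented by its probe set with the highest mean over the 4 arrays, giving 817 genes measured. Lists with at least 5 measured genes, 9 in number, were tested against the other named genes with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Counts of list members rest on that probe set alone, also for gst13, H1, expA4 and expB8, which have another probe set that was called. Members were also counted with p-values adjusted over the list alone.

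The rule for named genes, fixed before the data were examined, took the 10 largest positive and 10 largest negative differences with an adjusted p under 0.05, no overlap between the lines' arrays and a real gene name, 1 probe set per gene. It added up to 3 called members of each list by p, or the member with the smallest p as values only where none was called. It also added every called member (at most 10) of the lists for monolignols, lignin polymerization, cellulose and hemicellulose, and bm1 as values. The rule also listed bm3, C4H and CCoAOMT, for which no symbol was matched, so they are not analysed here. The genes expa2, expB7, bk2, PAL1, ccr2, pox1, myb31, opr7, aoc1, prp2, kn1 and lg3, and the outer cell layer and YABBY genes apart from yab14, fall outside the rule and were chosen after their values were seen. The same holds for gln1, gln2, gln5, Agp2, expA4, expB8, rs2, Hb2, GLB1, aba1 and cyclotide, and for the genes of other lists chosen after the data were seen. The DNA replication list was also added after the data were examined, but before the values of its members on the single arrays were seen.

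The fit was tested on simulated data with the spreads of the 11263 probe sets and 200 changed probe sets, 50 at each size. For F98908 against Cm489 it recovered 36% of changes of 1 log2 unit, 80% of changes of 2, 84% of changes of 4 and 100% of changes of 8. Of 164 simulated calls, 14 (8.54%) were unchanged probe sets, above the nominal 5%, and simulated data with nothing changed gave 0 limma calls. The 200 changed probe sets are far fewer than the 1722 called in the data, and their spreads were shuffled over the probe sets. The recovery and false call rates therefore need not hold for the real fit. Alternatives were another filter or none, a floor at log2 4, median centring, quantile normalization, an intensity trend, robust eBayes, a replicate block, F98908 as 1 sample, no cross-hybridising probe set types, a threshold of 0.01, each array left out, an estimated correlation between genes and the mean over a gene's probe sets. Crossed pairing, lists without members of another function (also without opr5) and a count over any other probe set of a sequence cluster were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.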

Results

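The series measured transcript levels in aerial material of 2 maize lines, Cm489 and F98908, in work on the diversity of the maize cell wall and on the digestibility of maize lines. Each line is represented by 2 arrays, and 11263 probe sets were bright enough to be tested. The labels give no digestibility value for either line, so the single comparison the design allows is between the lines themselves, taken as F98908 minus Cm489.

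The largest differences between the lines in named genes were in genes bright in one line and near background in the other. HRGP (LOC542371), a hydroxyproline-rich glycoprotein of the cell wall, reached 12.33 ± 0.18 in F98908 and 2.64 ± 0.15 in Cm489 (mean log2 ± SD, n = 2 arrays per line), at least 323-fold higher (adjusted p = 0.000284). A second probe set for the same target sequence was at 11.63 ± 0.23 and 2.87 ± 0.14. The ribosomal protein gene rpl30 (LOC541668) was at least 287-fold higher in F98908 (12.16 ± 0.01 against 2.26 ± 0.01, adjusted p = 0.000238). In the other direction zrp4, an O-methyltransferase gene first described in roots, was at 10.88 ± 0.15 in Cm489 and 2.81 ± 0.46 in F98908, at least 118-fold lower in F98908 (adjusted p = 0.000798). The beta-expansin gene expB5, of a family that loosens grass cell walls, rose by at least 16.5-fold in F98908, with 8.05 ± 0.57 against 2.14 ± 0.01 (adjusted p = 0.00261).

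Further genes among the largest increases in F98908 were PLTP, a phospholipid transfer protein (log2 difference 6.30 ± 0.82 SE, adjusted p = 0.0221), and PER42, a class III peroxidase (4.87 ± 0.44 SE, adjusted p = 0.00969). The linker histone gene H1 (LOC542385) differed by 7.13 on one probe set (adjusted p = 0.000273), but by 1.60 (adjusted p = 0.107) and -0.29 (adjusted p = 0.570) on its 2 others. PLTP likewise differed by -0.71 on its brighter probe set (adjusted p = 0.195). The largest decreases in named genes were those of gst13, a glutathione transferase, at least 177-fold lower on one probe set (2.73 ± 0.01 against 11.46 ± 0.33, adjusted p = 0.000373) with a difference of -0.11 on its other (adjusted p = 0.691), and of zrp4. The ribosomal protein gene RPS21 fell by 4.51 on the log2 scale (adjusted p = 0.000943), and Ann7, an annexin, fell by 4.07 (adjusted p = 0.00189). The MADS-box genes zap1 and m24 fell, zap1 by at least 3.99-fold (measured difference -3.50 ± 0.49 SE, adjusted p = 0.0260) and m24 by at least 4.13-fold (6.05 ± 0.85 and 1.93 ± 0.19, adjusted p = 0.0158). Neither was called with values under log2 4 set to 4 (adjusted p = 0.0783 and 0.0647). NIT2, a nitrilase, was at least 7.49-fold lower (6.91 ± 0.44 and 3.61 ± 0.47, adjusted p = 0.0136), and cpi2, a cystatin that inhibits cysteine proteinases, fell by 3.30 (adjusted p = 0.00996) and by 1.09 on its other probe set (adjusted p = 0.0133).

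Over all tested probe sets, limma called 819 higher and 903 lower in F98908, of which 583 and 602 differed at least 2-fold. Among the 1722 calls, 274 differed by at least 4 log2 units, and 116 had a mean under log2 4 in one line and over 8 in the other, 66 bright in F98908 and 50 bright in Cm489. The called probe sets include 144 with 1 gene symbol, 72 in each direction, and 1578 that are unnamed here. With the F98908 arrays taken as 1 sample, because they share an extract label, 248 were higher and 170 lower, and the counts were 543 and 536 without Cm489 array 1, 453 and 463 without Cm489 array 2, 257 and 176 without F98908 array 1 and 267 and 176 without F98908 array 2. Of the 33 named genes that were called, 9 were called in each of these fits and without a filter on dim probe sets: HRGP, rpl30, H1, expB5, zrp4, gst13, GST38, RPS21 and Ann7. The remaining named genes each lost the call in at least 1 of these fits, and all 33 kept their direction with each array left out. With F98908 as 1 sample, or with 1 array left out, the spread comes from the 2 arrays of the other line alone. H1 and gst13 were called on probe sets of the cross-hybridising types, so neither call was tested in the alternative without those types. None of their other probe sets was called.

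**Figure D1:**
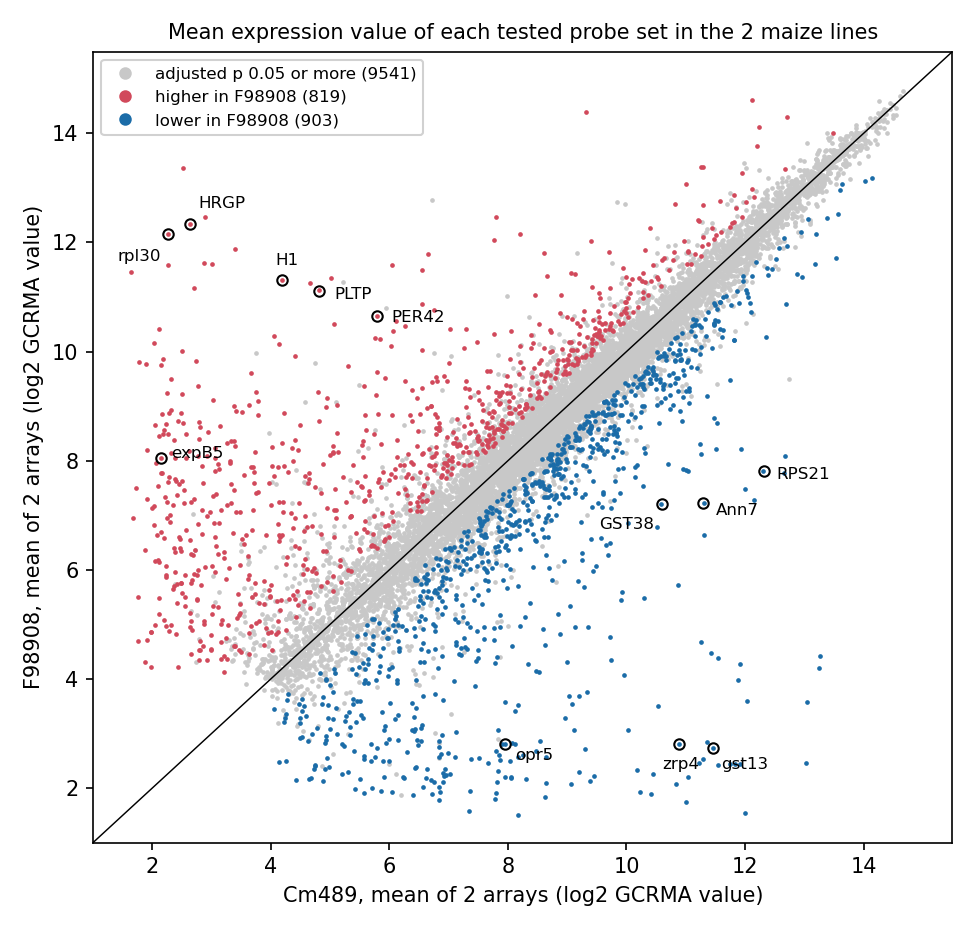
Mean log2 value of each tested probe set in Cm489 (x axis, 2 arrays) against F98908 (y axis, 2 arrays), with the 819 probe sets called higher in F98908 in red, the 903 called lower in blue and equal values on the line. HRGP and rpl30 lie at the upper left, and zrp4 and gst13 at the lower right, each far from the bulk of probe sets.

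Among the wall lists, the wall remodelling genes were higher in F98908. The list is made of expansins and a xyloglucan endotransglycosylase, which loosen or rebuild the wall. Its 11 measured genes had a median log2 difference of 1.63, with 9 of them positive (camera, adjusted p = 0.00867; adjusted p = 0.720 with an estimated correlation). With 1 probe set per gene, only expB5 and expB3 rose past the threshold over all probe sets, and 3 genes did when adjusted over the list alone, the third being expa2. The gene expB3 rose by 3.03 ± 0.30 SE (8.16-fold, adjusted p = 0.0118), whereas expa2 was at 3.97 ± 1.73 in Cm489 and 8.51 ± 0.25 in F98908 (adjusted p = 0.0528) and expB7 had a difference of 5.05 ± 1.68 SE (adjusted p = 0.139). The list was not called without a filter on dim probe sets (adjusted p = 0.0671) or with a mean over log2 6 (adjusted p = 0.0605). It also differed between arrays of a line, with a median of -0.65 for Cm489 array 1 minus array 2 and 0.32 for F98908 array 1 minus array 2. These medians lay at percentiles 0 and 99.99 of random lists matched on mean level. In both lines this shift went the opposite way to that of the outer cell layer, YABBY and DNA replication genes.

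Cellulose synthesis genes, which include the catalytic subunits of cellulose synthase and the COBRA-like gene bk2, showed small differences. Of 14 measured genes, CesA-1 and CesA-6 fell and 12 did not pass, with the same count of 2 adjusted over the list alone. CesA-1 went from 11.58 ± 0.13 in Cm489 to 10.91 ± 0.04 in F98908 (n = 2 arrays per line, difference -0.68, adjusted p = 0.0407), and CesA-6 from 11.16 ± 0.09 to 10.51 ± 0.08 (difference -0.65, adjusted p = 0.0405). Neither was called with F98908 as 1 sample (adjusted p = 0.234 and 0.225) or with any single array left out. The gene bk2 had a difference of 1.10 ± 0.34 SE (adjusted p = 0.123), and the list as a whole was not called (median -0.07, adjusted p = 0.683).

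The monolignol genes, which make the building blocks of lignin, gave 0 calls among 4 measured genes in limma's test, with 1 at an unadjusted p under 0.05, and 0 adjusted over the list alone. BM1 (LOC542663), the cinnamyl alcohol dehydrogenase whose loss gives brown midribs, was at 11.94 ± 0.17 in Cm489 (n = 2 arrays), and the difference was 0.06 ± 0.13 SE (adjusted p = 0.774). PAL1, a phenylalanine ammonia-lyase, differed by -0.02 ± 0.11 SE (adjusted p = 0.935), 4CL, which activates cinnamic acids with coenzyme A, by 0.75 ± 0.17 SE (adjusted p = 0.0691), and ccr2, a cinnamoyl-CoA reductase gene, by -0.33 ± 0.37 SE (adjusted p = 0.598). Of the 2 measured genes for lignin polymerization, the peroxidase gene PER42 rose from 5.79 ± 0.46 to 10.66 ± 0.69, and pox1 had a difference of -0.12 (adjusted p = 0.722), with 1 called over all probe sets and 1 adjusted over the list alone. RGP, a reversibly glycosylated protein and the only measured gene for hemicellulose synthesis, had a difference of -0.23 (adjusted p = 0.368).

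Among 7 genes matched as wall structural proteins, HRGP and AGP2 rose and 5 did not pass, with the same 2 adjusted over the list alone. AGP2 (LOC542737) is an ADP-glucose pyrophosphorylase subunit of starch synthesis that shares its symbol with the arabinogalactan proteins. It rose by 0.93 ± 0.11 SE (limma, adjusted p = 0.0193). Agp2 (LOC542072), also a gene of another function, had a difference of -0.04 (adjusted p = 0.920). The list's median was -0.04 while its mean was 1.24 and the test pointed upward, without a call (adjusted p = 0.604). The 2 measured regulators of secondary walls, knox7 (-0.32, adjusted p = 0.200) and myb31 (-0.16, adjusted p = 0.360), were not called.

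**Figure D2:**
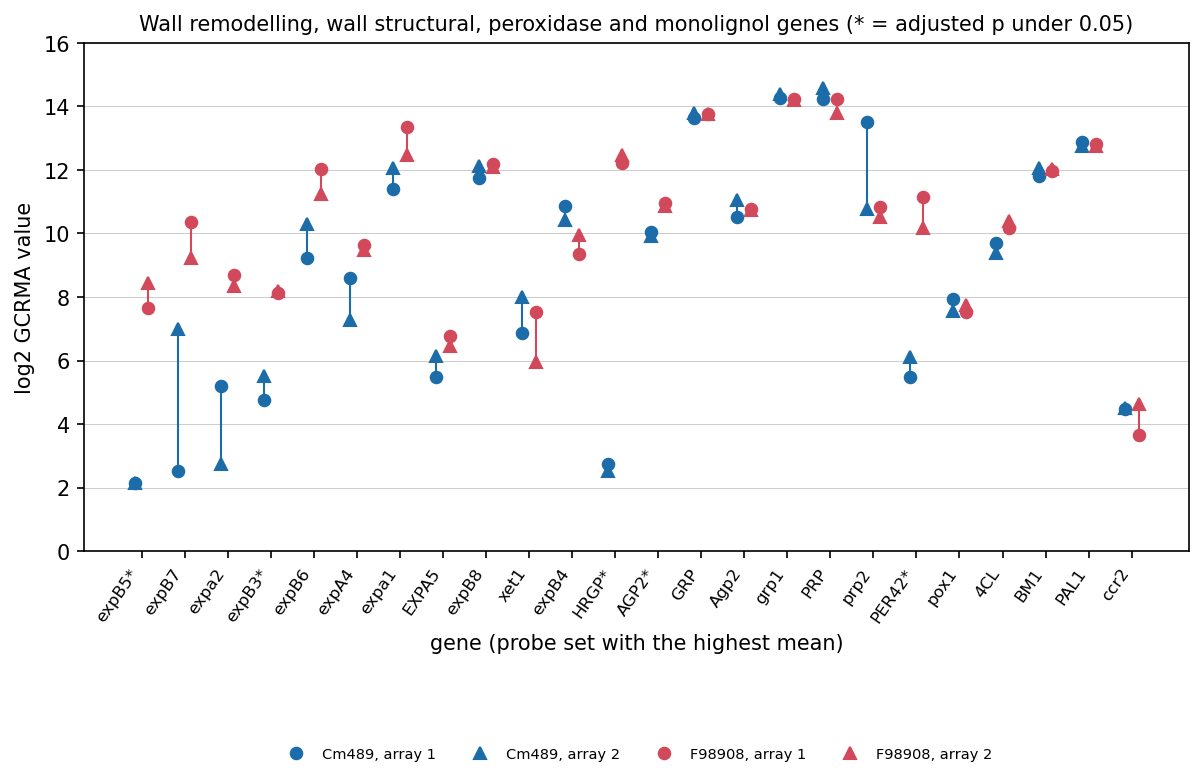
Log2 value on each of the 4 arrays (circles, array 1; triangles, array 2; a line joins the arrays of a maize line) for the measured genes of 4 wall lists, each list ordered by difference, with called genes starred. In HRGP and expB5 the lines are at least 16.5-fold apart, while BM1 and PAL1 overlap between the lines, and expB7 and prp2 differ widely between the 2 Cm489 arrays.

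The list for jasmonate synthesis, matched by symbol, was lower in F98908. Of 7 measured genes 4 fell and 3 did not pass, and 5 were called when adjusted over the list alone (median -1.17; camera, adjusted p = 0.00867; adjusted p = 0.720 with an estimated correlation). The gene lox3, a 9-lipoxygenase and so of a kind that does not feed jasmonate synthesis, was at least 3.78-fold lower (5.92 ± 0.20 in Cm489, 3.14 ± 0.44 in F98908, adjusted p = 0.0115), and the oxophytodienoate reductase gene opr5 at least 15.4-fold lower (7.95 ± 1.19 and 2.81 ± 0.38, adjusted p = 0.0209). The allene oxide synthase gene aos1 fell by 1.07 ± 0.12 SE (adjusted p = 0.0165). The fourth, opr7, fell by 1.17 (adjusted p = 0.0465) and is named after its value was seen. The list stayed called without lox3 (adjusted p = 0.0223) but not without lox3 and opr5, whose part in jasmonate synthesis is unsure (adjusted p = 0.0853), both chosen after seeing the data. It also was not called without a filter on dim probe sets (adjusted p = 0.0671) or with a mean over log2 6 (adjusted p = 0.0605), and lox3 alone of the named 3 was called with F98908 as 1 sample (adjusted p = 0.0455). The list also differed between arrays of a line, with a median of 0.31 for F98908 array 1 minus array 2 (percentile 99.7 of matched lists; aoc1 at 9.98 and 8.12) and -0.09 for Cm489.

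**Figure D3:**
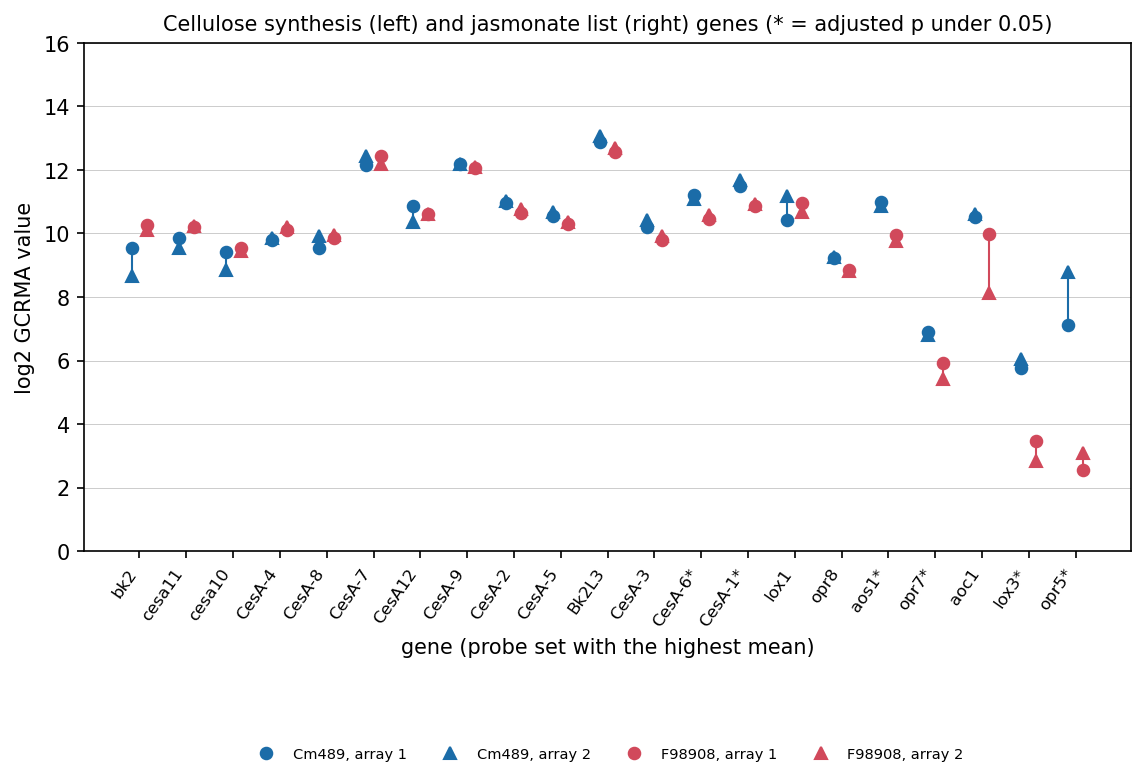
Log2 value on each of the 4 arrays (circles, array 1; triangles, array 2) for 14 cellulose synthesis genes, left, and the 7 genes of the jasmonate list, right, each ordered by difference, with called genes starred. The cellulose genes stay within 1.10 log2 units between the line means, and lox3 and opr5 show the widest gaps in the jasmonate list.

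Glutathione transferases, which conjugate glutathione to toxic compounds, moved in both directions. By the brightest probe set of each gene, 6 of 19 rose, 1 fell and 12 did not pass. The 12 include gst13, although its dimmer probe set was called. Adjusted over the list alone, 6 rose and 5 fell. The gene gst16 was at least 7.31-fold higher in F98908 (2.29 ± 0.01 in Cm489, 6.87 ± 0.69 in F98908, adjusted p = 0.00745), gst10 rose by 3.84 ± 0.26 SE (adjusted p = 0.00495), gst5 by 3.91 ± 0.58 SE (adjusted p = 0.0294), and gst6 was at least 13.3-fold higher (3.55 ± 1.36 and 7.74 ± 0.30, adjusted p = 0.0403). GST38 fell by 3.38 ± 0.10 SE (adjusted p = 0.000613). The list's median was -0.11 and its mean 0.71, and its test gave no call (adjusted p = 0.691).

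In nitrogen assimilation, the 2 called genes, both for glutamine synthetase, went opposite ways. GLN6 rose by 1.81 ± 0.28 SE (adjusted p = 0.0326), and gln3 was at least 6.80-fold lower in F98908 (6.77 ± 0.74 in Cm489, 3.72 ± 0.11 in F98908, adjusted p = 0.0224). The other 4 of 6 measured genes did not pass, among them the glutamine synthetase genes gln5 (-0.42), gln1 (-0.49) and gln2 (-0.53). Adjusted over the list alone 3 genes were called, and the list was not called (camera, adjusted p = 0.604). Among 8 genes for starch and sucrose, AGPLS3, a large subunit of ADP-glucose pyrophosphorylase, fell by 0.81 ± 0.13 SE (adjusted p = 0.0368), and so did Agpat4, by 0.62 ± 0.10 SE (adjusted p = 0.0352). Agpat4 is an acyltransferase of glycerolipid synthesis that matched the list by its symbol alone, and its other probe set differed by -0.17 (adjusted p = 0.553). Adjusted over the list alone the count was also 2, and the list was not called (adjusted p = 0.683).

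Of 6 heat shock genes, hsp22, a small heat shock protein, was at least 4.25-fold higher in F98908 (3.48 ± 0.43 and 6.09 ± 0.28, adjusted p = 0.0146), and it was also the only member called over the list alone; the list was not called (adjusted p = 0.683). The dehydrin gene dhn2 (LOC542251, also listed as dehydrin3), the single measured gene of the dehydration list, rose on all 3 of its probe sets, by 1.33, 1.86 and 2.63 (adjusted p = 0.00852, 0.00811 and 0.0116). The only measured gene for terpene synthesis, an1, an ent-copalyl diphosphate synthase of gibberellin synthesis, rose by 1.47 ± 0.13 SE (adjusted p = 0.00969). In each of these 2 lists the gene was also called over the list alone.

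Markers of leaf cell types and other tissues gave few calls. The mesophyll list (3 genes) and the bundle sheath list (2 genes) had 0 limma calls over all probe sets and 0 over the list alone, with 2 and 0 at an unadjusted p under 0.05: pdk1, pyruvate phosphate dikinase, had a difference of 0.59 (adjusted p = 0.153) and rbcS, the Rubisco small subunit, one of -0.47 (adjusted p = 0.175). The meristem and leaf identity list has 10 genes, of which Hb2 has another function. Limma called 0 of them, also over the list alone, and 0 had an unadjusted p under 0.05. Their smallest p was that of yab14, at 3.13 ± 1.59 in Cm489 and a mean of 5.59 in F98908 (adjusted p = 0.188). The list's median of -0.14 and its mean of 0.32 differ in sign, and it was not called (adjusted p = 0.889). In the kernel storage list the zein gene zp27 had a difference of 0.48 (limma, adjusted p = 0.0841). It lay near log2 4, at 4.43 in Cm489 and 4.91 in F98908. The other gene, GLB1, has another function. Limma called 0 of 2 genes over all probe sets, with 1 at an unadjusted p under 0.05 and 1 adjusted over the list alone. The root list had zrp4 as its only measured gene, called in both ways of adjusting.

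Of the other lists, limma called 0 of 4 benzoxazinoid genes (0 at an unadjusted p under 0.05), with bx1, the first enzyme of the pathway, at 1.36 ± 0.48 SE (adjusted p = 0.155). It called 0 of 2 pathogenesis related genes (0 unadjusted), and PR-5, a thaumatin-like protein, was at 5.94 ± 4.30 in Cm489 and 10.79 ± 0.60 in F98908 (adjusted p = 0.238). By the brightest probe set of each gene, it called 0 of 2 genes each in histones (1 unadjusted, his2b5 at -0.76, adjusted p = 0.151), cell division (0 unadjusted, cyclin-A1 at 0.78, adjusted p = 0.309) and cuticle and wax (1 unadjusted, gl8 at -0.77, adjusted p = 0.0717). Of the histone genes, H1 was called only on a probe set with a lower mean over the 4 arrays. In F98908 that probe set was the brighter, at 11.32 against 10.34 on the one counted. The single flavonoid gene, chs1, a chalcone synthase, had a difference of 0.33 (adjusted p = 0.119). Adjusted over the list alone, gl8 and chs1 were called.

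The arrays of a line were closer to each other than to the arrays of the other line. The median absolute difference over the tested probe sets was 0.206 between the 2 Cm489 arrays and 0.131 between the 2 F98908 arrays, and 532 and 221 probe sets differed by more than 1 log2 unit. Between arrays of different lines the median absolute difference ran from 0.282 to 0.351, and 1695 to 1978 probe sets passed 1 log2 unit. The lists and genes named here for differences within a line were chosen after their values were seen. Lists also differed within a line, array 1 minus array 2: benzoxazinoid genes by a median of -0.86 and nitrogen assimilation genes by -0.56 in Cm489, and heat shock genes by 0.21 in F98908. Genes that set the Cm489 arrays apart include ocl1, a homeodomain gene of the outer cell layer, at 8.43 on array 1 and 4.12 on array 2, and yabby15, of the YABBY family of leaf polarity genes, at 8.33 and 5.69. The largest differences between the Cm489 arrays in named genes went the other way, in aba1 (2.33 on array 1, 11.13 on array 2) and cyclotide (3.60 and 9.80). On the F98908 arrays aba1 was at 13.01 and 12.55, and cyclotide at 8.08 and 8.21. In Cm489 PR-5 stood at 2.90 and 8.99, and expB7 at 2.51 and 6.98, which widens the error of both in the comparison of the lines.

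**Figure D4:**
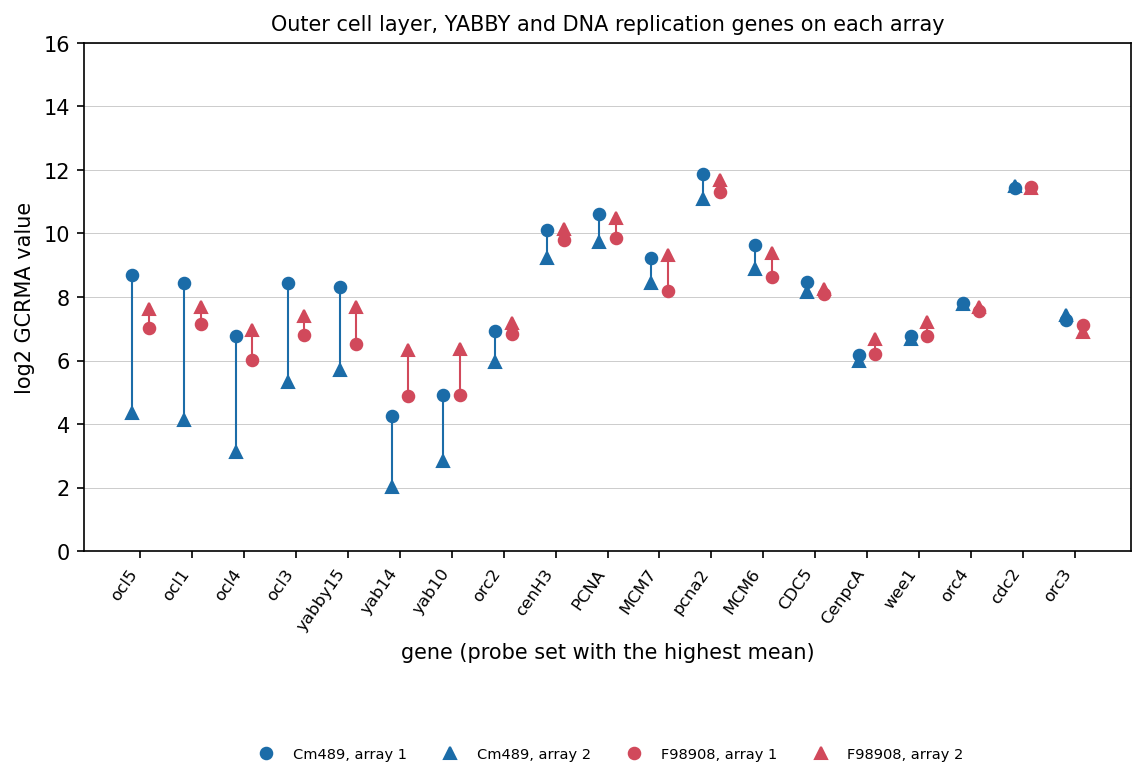
Log2 value on each of the 4 arrays (circles, array 1; triangles, array 2) for outer cell layer, YABBY and DNA replication genes, each set ordered by Cm489 array 1 minus array 2. All 4 outer cell layer genes and all 3 YABBY genes are higher on array 1 than array 2 in Cm489, and lower in F98908.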

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

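All 33 named genes that were called kept their direction under every alternative in which they were tested, and of all 47 named genes BM1 alone turned (-0.055 to 0.18 with 1 array left out, below 0 without Cm489 array 1). The counts of higher and lower probe sets, and of those at least 2-fold higher and lower, stayed within 1.5 times under a floor at log2 4, median centring, quantile normalization, an intensity trend, robust eBayes and without cross-hybridising probe set types. Without a filter, 370 and 345 were at least 2-fold higher and lower. With a mean over log2 6, for fewer probe sets tested, 505 were higher, and 313 and 375 at least 2-fold higher and lower. Taking F98908 as 1 sample, which leaves fewer samples, gave 248 higher and 170 lower, all at least 2-fold, with 410 of its 418 calls shared with the 1722. A threshold of 0.01 gave 318 and 266, also all at least 2-fold. With 1 array left out, where the lone array is assumed to vary like the other line, 257 to 543 were higher and 176 to 536 lower, and 257 to 521 and 176 to 507 were so by at least 2-fold.

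The replicate numbers do not pair the samples: across probe sets the array 1 minus array 2 differences of the lines correlated at r = -0.365 (probe sets are not independent). A replicate block gave 409 higher and 371 lower, 371 of them at least 2-fold lower. The crossed pairing, chosen after seeing the data, gave 889 and 973.

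Wall remodelling and jasmonate, the 2 lists called, gave 0 camera calls without a filter (adjusted p = 0.0671 for both), with a mean over log2 6 (0.0605 for both) and with an estimated correlation (0.720 for both), and were called in the other settings that bear on their test (13 of 16 for wall remodelling), except jasmonate without lox3 and opr5 (0.0853, 1 list called, 14 of 18); the cause was not tested. Robust eBayes and a threshold of 0.01 do not enter camera and are not counted. The estimated correlation rests on 2 residual degrees of freedom. It was 0.0168 for wall remodelling and 0.451 for jasmonate, against the preset 0.01. With it every list but meristem stood at the same adjusted p in camera, 0.720. That setting therefore could not set wall remodelling and jasmonate apart from the other lists. With 1 array left out their adjusted p ran from 0.00119 to 0.0257 and from 0.000232 to 0.0486, with 2 lists called each time. No other list was called by camera in any setting. The meristem list turned upward with crossed pairing (adjusted p = 0.984), without Cm489 array 2 and without F98908 array 1 (0.697 to 0.829 over the arrays left out), and the glutathione transferases downward with a mean over log2 6 (0.684). Limma's fry, planned beside camera, tests a list on its own rather than against the other genes. Its unadjusted p was 0.000642 for wall structural proteins, 0.00314 for glutathione transferases, 0.0159 for starch and sucrose and 0.0336 for cellulose synthesis. Of the 7 wall structural members only 3 were positive, and those called were HRGP and AGP2, the latter a gene of another function. For wall remodelling fry gave 0.0155, for jasmonate 0.0265, and for the remaining lists 0.145 to 0.607. Without a filter, dim probe sets with little spread brought the array differences down to 0.0999 in Cm489 and 0.0631 in F98908. Signal over background limits folds whose dimmer line lies under log2 4 to bounds.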

Other observations

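Aquaporins, a list chosen after the data were seen like the others in this paragraph, were lower in F98908 for 6 and higher for 3 of 23 measured genes, with a median difference of -0.76. The plasma membrane members pip2b (-1.85, adjusted p = 0.0136) and pip2c (-1.17, adjusted p = 0.0263) fell, while PIP1-3 rose by 1.17 (adjusted p = 0.0306), the vacuolar TIP1-2 was at least 2.97-fold higher in F98908, at 5.57 ± 0.60 (n = 2 arrays, measured difference 3.07 ± 0.32 SE, adjusted p = 0.0140), and NIP2-3 rose by 2.33 (adjusted p = 0.00280). Among 21 chromatin genes 7 rose and 2 fell, including the histone deacetylase gene Hda1 (1.21, adjusted p = 0.0112), the methyl-CpG-binding gene mbd109 (0.75, adjusted p = 0.0427) and the SET domain genes sdg118 (1.34, adjusted p = 0.0169) and sdg110 (-1.41, adjusted p = 0.00530). Of 9 cytokinin response regulators, RR6 was at least 6.39-fold higher in F98908 (3.36 ± 0.31 in Cm489, 6.68 ± 0.16 in F98908, limma, adjusted p = 0.00376). The gene crr1 rose by 0.74 (4.12 ± 0.15 and 4.87 ± 0.15, adjusted p = 0.0493). RR4 was at least 1.04-fold lower (4.05 ± 0.06 and 3.44 ± 0.04, adjusted p = 0.0376). Both crr1 and RR4 lay near the filter at log2 4. In the 11 ribosomal protein genes only rpl30 and RPS21 were called, and the others lay between -0.36 and 0.35. Of 12 tubulin genes, tub4 (-0.91, adjusted p = 0.0302) and tub6 (-0.63, adjusted p = 0.0445) fell and 1 rose. Between the F98908 arrays, array 1 minus array 2, the medians of the chromatin and tubulin lists were both -0.12 (percentiles 1.71 and 0.1 of lists matched on mean level). These lists were not tested as sets.

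Of the tests below, all but that of the DNA replication list in Cm489 were chosen after the results were seen. That list was set before the values of its members were seen, but after histone, cyclin and orc1 genes had been seen higher on array 1 of Cm489, and orc1 was left out of it.

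The Cm489 arrays differed in outer cell layer genes (4 of 4 higher on array 1, median 3.97) and YABBY genes (3 of 3, median 2.25), with ocl4, yab10 and yab14 under log2 4 on array 2. A different share of young dividing tissue in the samples may account for this, as a hypothesis. It needs DNA replication and cell cycle genes to be higher on array 1 as well, and 10 of 12 were. Their median of 0.52 lay at percentile 100 of 10000 lists matched on mean level. The matched lists, here and wherever a percentile is given, were drawn from unrelated probe sets. The members of a gene list can vary together, so such percentiles can overstate how unusual a shift is. The meristem and leaf identity list had a median the other way (-0.24, percentile 2.99), but its members were mixed, with 4 of 10 higher on array 1. Those higher include yab10 and yab14, of the YABBY genes themselves, and rs2, at 6.68 on array 1 and 5.41 on array 2. Those lower include kn1 (10.77 and 11.51), lg3 (7.18 and 8.48) and Hb2, a gene of another function (8.74 and 9.84). The hypothesis stays open. RNA degradation is not decided either: the gap between 3′ and 5′ control probe sets differed more between the Cm489 than the F98908 arrays for 2 of 3 control genes (actin 0.279 against 0.220, ubiquitin 0.0528 against 0.0332) and less for GAPDH (0.0106 against 0.0593), by margins small beside the shifts above. Poly-A controls also differed by -0.57 for array 1 minus array 2, and no biological difference between the Cm489 plants is given by the design.

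The F98908 arrays were closer to each other than the Cm489 arrays, with 0.636 of their median absolute difference, and they share an extract label. If both came from 1 RNA extract, the replication list should not differ between them, yet its median of -0.37 lay at percentile 0.01 of the matched lists, and the YABBY genes differed by -1.44. Taken alone this argues against 1 extract, though the percentile ignores that these genes can vary together. The poly-A controls, which are added to the sample RNA, differed in the opposite direction (0.26), as they did in Cm489. A labelling effect on 1 extract and separate extracts therefore cannot be told apart with 4 arrays.

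Probe sets near background in one line and bright in the other may reflect a difference in the probed sequence or gene copy rather than in the whole output of the gene. Of 21 such sequence clusters with another measurable probe set, 6 (28.6%, exact 95% interval 11.3% to 52.2%) had it differ by at least 1 log2 unit the same way, taking the first other by ID, against 24 of 139 clusters (17.3%) for other probe sets called at least 2-fold (Fisher's exact test, two-sided, p = 0.234). Counting a cluster if any other probe set followed, 8 of 21 (38.1%, 18.1% to 61.6%) did, against 34 of 139 (24.5%). Both intervals for the 21 clusters include 50%. Clusters of the other called probe sets also seldom followed (17.3%), but the sets are not alike. The median size of the first difference was 2.12 log2 units there and 6.37 in the 21 clusters. At the same bound of 1 log2 unit fewer of the smaller differences could be followed, and a cluster could enter both sets. The comparison and its Fisher's exact test therefore do not show what share to expect without a sequence or copy difference. Sequence or copy differences and line-specific expression, the open biological explanation, cannot be told apart by these counts.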
